A study of Drosophila melanogaster with 24 samples.

How the data were processed

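RNA was measured in 24 libraries of sorted CLK856 neurons, 4 genotypes at 2 ages with 3 libraries each, prepared by Smart-seq3 from about 750 pg of cDNA per library. The deposited count table holds counts, whole UMIs per library, for 15610 genes, 527 of them without a UMI. Its values are unnormalized per the labels and their whole-number form. The authors aligned reads with STAR to dm6, per the submitters' processing notes. The version, annotation and UMI counting program are not given in the sources used here. How reads shared between near-identical or overlapping genes were counted is thus not known. This is marked for near-identical copies and Opa1, not for overlapping genes such as cry, tim and para.

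The authors deposited 6 comparison tables made with DESeq2, per the submitters' processing notes and without a version. In these deposited tables the fold changes are log2 values, per the file headers, and each p-value and adjusted p-value was computed by the authors with DESeq2, per the file headers. The baseMean, standard error and Wald statistic columns of the deposited tables were taken as a score each, per the file headers. The baseMean values are equal in the 3 tables of an age for 10102 of 10102 genes in young and 10424 of 10424 in old flies, within a relative tolerance of 1e-06, so the 12 libraries of an age were scaled together. These tables were used only for a comparison with the calls made here.

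Counts were analysed in R 4.3.3. The test for each comparison was the quasi-likelihood F test of edgeR 4.0.16, with TMM scaling, its filter on low counts by group (filterByExpr), robust dispersions and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Scaling factors over all libraries were 0.919 to 1.132, and library depth was 684175 to 2889269 UMIs. The standard error of a log2 fold change is its size divided by the square root of F. Levels are TMM-scaled CPM, as mean ± SD of the 3 libraries. Where a group had no UMI a fold is a lower bound against a floor of 3 counts over the group.

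Comparisons were each mutant against Cas9 at each age, old against young Cas9, the difference of each mutant effect between ages, Marf-mut against Opa1-mut at each age, and Drp1-mut against the mean of both fusion mutants at each age. Because the 3 libraries of a group share a cell suspension, each mutant was also tested on counts summed per suspension, with age and genotype as terms and 3 residual degrees of freedom. Replicate numbers were checked for pairing across groups and do not pair libraries.

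27 gene lists, fixed before the data were examined, were tested with camera on voom values (limma 3.58.1) with the preset correlation of 0.01, and again with an estimated correlation. They cover mitochondrial dynamics, ATF4 targets, one-carbon metabolism, the mitochondrial and endoplasmic reticulum unfolded protein responses, autophagy and mitophagy, glycolysis, the tricarboxylic acid cycle and nuclear and mitochondrial DNA genes of the respiratory chain. They also cover mitochondrial and cytosolic ribosomes, the proteasome, heat shock, oxidative stress, innate immunity, Jun kinase signalling, lipid metabolism, the core clock, neuropeptides, synaptic release and ion channels. The remaining lists are markers of glia, photoreceptors, fat body and hemocytes, other neurons and inserted constructs. After the symbols were seen only member names were adapted to the spelling of the table.

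Genes are named by a rule set at the same time. Targets are given in every group. Named next are up to 10 rises and 10 falls with the largest fold among called genes whose libraries do not overlap and whose higher group averages at least 20 UMIs, leaving out unnamed genes, antisense and long noncoding RNA and mitochondrial rRNA. Up to 4 called members of each called list follow, then core clock genes and the stress genes crc, Thor, Ldh, Nmdmc, Ets21C, Pink1, Hsp60A and w. The 5 called genes with the smallest p are named in interaction, direct and suspension tests. The report prints a part of these genes.

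Alternatives set at the same time were DESeq2 size factors, total count scaling, no filter on low counts, DESeq2 1.42.0 as the test, thinning to equal depth, a replicate block, all 24 libraries in a single fit, an estimated correlation for lists, and leaving out each library or suspension. Chosen after seeing the data were a fit of the 12 libraries of an age, leaving out mitochondrial and ribosomal RNA, and log2 depth as a covariate. When a group is left with 2 libraries or 1 suspension, it is assumed to vary like the others.

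The tests were run on simulated libraries without suspension differences, so real error rates are unknown. Of genes with a 4-fold change, 97%, 96.1% and 94.8% were called in young Drp1-mut, Marf-mut and Opa1-mut. In the old ones 95%, 98% and 99% were. For a 2-fold change the shares are 68.8%, 81.9%, 76%, 72.6%, 79.4% and 85.4% in the same order. False calls were 19, 13, 8, 17, 7 and 17, or 10.5%, 6.9%, 4.6%, 9.4%, 3.9% and 8.6% of the calls, where 5% is nominal. Of 2-fold differences between ages 36%, 48.5% and 49% were called for Drp1-mut, Marf-mut and Opa1-mut. With 20 simulations per pair, overlaps between mutants of an age were compared with data in which no gene is changed and only the controls are shared. Gene positions come from the Ensembl release 115 annotation, in which 14980 symbols were found and 621 were not. Genome sequence, splicing and editing were not analysed here.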

Results

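The libraries come from GFP-labelled clock neurons of male flies in which CLK856-Gal4 drives Cas9 and eGFP, alone (Cas9) or with guide constructs against Drp1, Marf or Opa1 (Drp1-mut, Marf-mut, Opa1-mut). Drp1 is the GTPase that divides mitochondria, Marf is the mitofusin that joins outer membranes, and Opa1 joins inner membranes. There are 4 genotypes at 2 ages, about 15 days (young) and about 35 days (old), which gives 8 groups of 3 libraries. Each library is a sorted pool of about 1000 cells collected at ZT14 and sequenced as 5' UMI counts. Young Cas9 libraries held 1791332, 1583625 and 2141193 UMIs in replicates 1 to 3, and young Drp1-mut libraries held 1318960, 1680324 and 2889269. Young Marf-mut libraries held 1406296, 1328007 and 2104854 UMIs, and young Opa1-mut libraries held 1315343, 1461912 and 1525456. Old Cas9 libraries held 1313809, 1286609 and 1109778 UMIs, and old Drp1-mut libraries held 1148217, 767438 and 684175. Old Marf-mut libraries held 1394517, 1532339 and 1735212 UMIs, and old Opa1-mut libraries held 1492083, 1468850 and 1843669. The neuropeptide gene Pdf, made by the ventral lateral clock neurons, stood at 11800 ± 3780 (SD, n = 3) CPM in young Cas9 and 11400 ± 1380 in old Cas9. The clock gene tim stood at 837 ± 67.4 CPM in young Cas9 and 908 ± 78.5 in old Cas9. The glial gene repo stood at 7.36 ± 3.53 CPM in young Cas9 and 7.32 ± 2.94 in old Cas9, and the peptide gene Hug at 4510 ± 2370 and 8250 ± 258.

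The 3 libraries of a group were sorted from a single cell suspension of 80 to 100 brains. Every test between groups of libraries therefore measures the spread between sorted pools of the same suspension, and a difference between suspensions cannot be told from a difference of genotype or age. The tests with 1 value per suspension, given near the end, are the only ones in which suspensions are the replicates.

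Drp1 lies on chromosome 2L from 2581281 to 2585430, Marf on X from 6365949 to 6370924 and Opa1 on 2R from 14230611 to 14235449 (release 6 of the genome). Their transcripts were compared in every group. 5' UMI counts show how much transcript is present and do not show whether bases were edited, so a cut gene can keep its transcript. Drp1 stood at 136, 136 and 163 CPM in young Cas9 and 165, 153 and 162 in old Cas9. In Drp1-mut it stood at 118, 73.8 and 105 CPM when young and at 89.8, 97.9 and 65.9 when old. Young Marf-mut and Opa1-mut held Drp1 at 133, 152 and 159 and at 165, 141 and 128 CPM, and the old ones at 152, 160 and 147 and at 135, 121 and 136. Marf stood at 161, 128 and 143 CPM in young Cas9 and 137, 141 and 136 in old Cas9. In Marf-mut it stood at 103, 108 and 145 CPM when young and at 105, 119 and 123 when old. Young Drp1-mut and Opa1-mut held Marf at 118, 114 and 129 and at 137, 139 and 135 CPM, and the old ones at 122, 115 and 136 and at 127, 116 and 145. Opa1 stood at 159, 129 and 146 CPM in young Cas9 and 150, 147 and 152 in old Cas9. In Opa1-mut it stood at 88.8, 128 and 91.7 CPM when young and at 95.9, 95.5 and 90.3 when old. Young Drp1-mut and Marf-mut held Opa1 at 132, 152 and 142 and at 158, 163 and 173 CPM, and the old ones at 144, 145 and 132 and at 145, 153 and 181.

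Drp1 fell in old Drp1-mut (log2 fold change -0.89, SE 0.16, adjusted p = 0.00619), and Opa1 fell in old Opa1-mut (-0.68, SE 0.12, adjusted p = 0.000363). Marf was not called in old Marf-mut (-0.27, SE 0.12, adjusted p = 0.228). In young flies no target was called, with Drp1 at -0.53 (SE 0.17, adjusted p = 0.76), Marf at -0.24 (SE 0.15, adjusted p = 0.668) and Opa1 at -0.46 (SE 0.15, adjusted p = 0.128). Without replicate 2 of young Opa1-mut the Opa1 value is -0.65 and is called. It is also called at -0.46 with all 24 libraries in a single fit and at -0.48 without the filter on low counts. With log2 depth as a covariate the old calls ended, at -0.78 (adjusted p = 0.611) for Drp1 and -0.58 (adjusted p = 0.207) for Opa1. 3 annotated genes overlap Opa1 on its strand, so reads from them can count toward it.

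**Figure D1:**
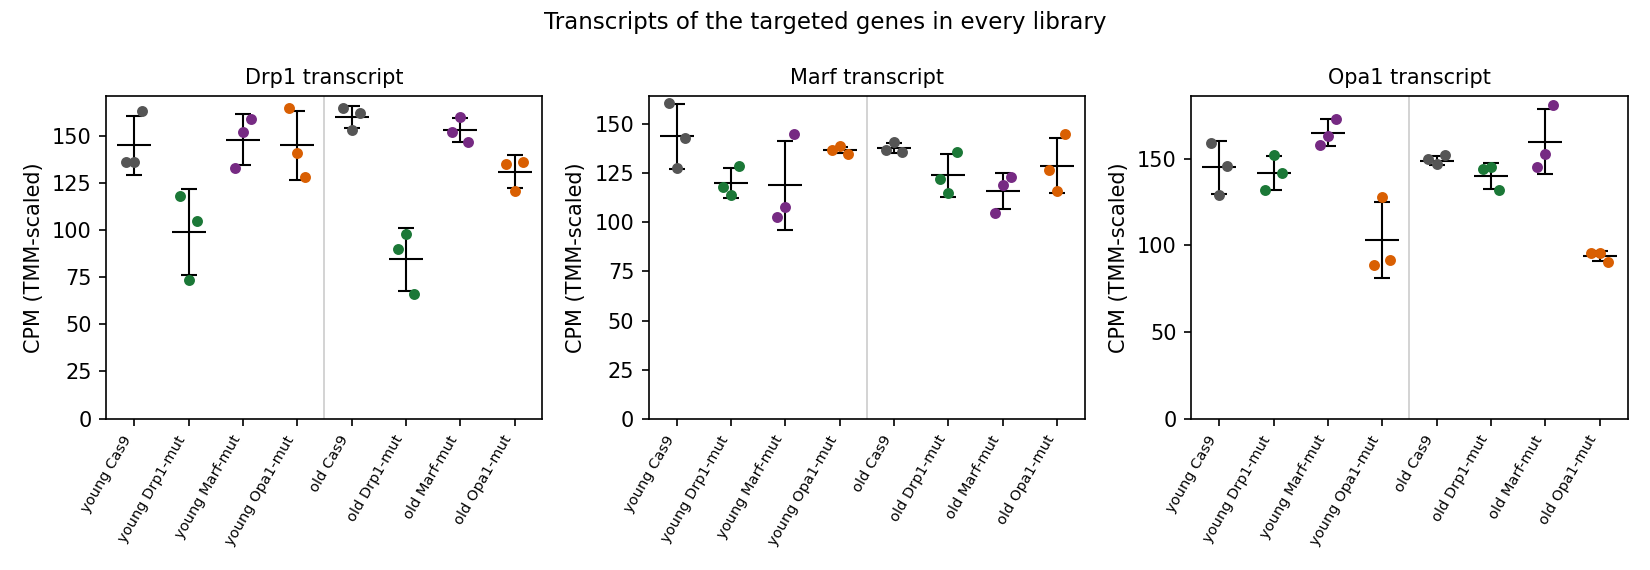
CPM of Drp1, Marf and Opa1 in each library of the 8 groups, where points are libraries, bars are means and whiskers are SD (n = 3). In old flies each target was lower in all 3 libraries with its guides than in any Cas9 library.

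Young Drp1-mut against young Cas9 asks what differs at about 15 days in the line with guides against Drp1. Lactate dehydrogenase (Ldh), the enzyme that turns pyruvate into lactate, rose. The colour genes yellow (y) and white (w), which also serve as markers of inserted constructs, rose as well. The transcript of mthl8, a Methuselah-like receptor gene, was absent. With a preset correlation only, and not with an estimated correlation, transcripts encoded by mitochondrial DNA and ATF4 target genes, whose products answer mitochondrial stress, stood higher as lists.

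In young Drp1-mut y rose (log2 fold change 4.64, adjusted p = 0.00576; 229 ± 69.6 against 9.11 ± 5.26 CPM, SD, n = 3). Ldh rose (2.14, SE 0.28, adjusted p = 0.0194; 75.1 ± 25.3 against 17.5 ± 4.27 CPM), and w rose to 70.7 ± 11.2 from 30.8 ± 1.59 CPM (adjusted p = 0.0112). mthl8 went from 63 ± 9.49 CPM to 0 UMIs, at least 126-fold lower (adjusted p = 5.56e-06). Outside the naming rule, and chosen after their values were seen, the other called genes are CG34423, which is higher (5.37, SE 0.48, adjusted p = 0.000155), and lncRNA:CR46393, which is lower. crc, the fly ATF4, was not called (-0.08), nor were Thor (0.85, adjusted p = 0.997), Pink1 (-0.34, adjusted p = 0.885) and the clock gene vri (0.43, adjusted p = 0.95).

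Among the lists in young Drp1-mut, the 13 transcripts of mitochondrial DNA stood higher (median 0.48, adjusted p = 7.96e-07; adjusted p = 0.608 with an estimated correlation), with none called singly, and 4 risen with log2 depth as a covariate (median 0.44). Their mean log2 CPM is 12.15 and 12.07 in replicates 1 and 2 but 11.1 in replicate 3, the deepest, where young Cas9 has 11.28, 11.67 and 11.14. ATF4 targets stood higher (median 0.10, adjusted p = 0.0325; 0.596 if estimated), and 1 of 17, Ldh, rose both in the test and adjusted over the list alone. Core clock genes stood higher (median 0.22, adjusted p = 0.0255; 0.642 if estimated), as did cytosolic ribosome genes (0.07, adjusted p = 0.0255; 0.926 if estimated), which turned lower without replicate 1 of young Drp1-mut (adjusted p = 0.167). Tricarboxylic acid cycle genes stood lower (median -0.14, adjusted p = 0.0112; 0.596 if estimated). Chaperones of the mitochondrial unfolded protein response stood lower (-0.19, adjusted p = 0.0181; 0.596 if estimated), and so did heat shock genes (-0.19, adjusted p = 0.00111; 0.596 if estimated). Mitochondrial dynamics genes stood lower (-0.08, adjusted p = 0.0311; 0.711 if estimated). Markers of other cells stood higher too, with photoreceptor genes (3 tested, median 1.77, adjusted p = 0.0181; 0.608 if estimated) and 2 of them adjusted over the list alone. Fat body and hemocyte genes followed (7 tested, median 0.63, adjusted p = 0.0309; 0.608 if estimated). Replicate 3 of young Drp1-mut holds these markers, with ninaE at 34.8, Hml at 45.5 and Col4a1 at 51.6 CPM. The marker genes of the constructs, y and w, rose as a list of 2 (adjusted p = 1.09e-08; 0.165 if estimated), with 1 called under total count scaling.

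edgeR called 6 of 7220 genes in young Drp1-mut, 4 higher and 2 lower, and DESeq2 called 12. The count was 3 without replicate 1 and 2 without replicate 3 of young Cas9, and 3 without replicate 2 and 43 without replicate 3 of young Drp1-mut. Under total count scaling 4 rose and 4 fell, 50% against 66.7% rising, and with log2 depth as a covariate 20 genes were called. Of the 4 called genes named by rule only mthl8 kept its call in every omission and every alternative.

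Young Marf-mut against young Cas9 asks the same of the line with guides against Marf. The heat shock gene Hsp68 and the co-chaperone gene starvin (stv) fell, and their list stood lower with a preset correlation but not with an estimated correlation. Cryptochrome (cry), the blue-light receptor of clock neurons, fell, and so did the actin gene Act42A and the synaptic vesicle gene Syngr. The citrate synthase gene knockdown (kdn), the Toll-induced gene BomT2 and the sodium/proton exchanger gene Nhe3 rose.

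In young Marf-mut y rose (log2 fold change 4.23, adjusted p = 9.7e-08) and w rose (1.65, adjusted p = 3.32e-05). The filamin-like gene jbug rose (2.06, adjusted p = 0.0181), with BomT2 (2, adjusted p = 0.0327), kdn (1.1, adjusted p = 0.0333), Nhe3 (0.71, adjusted p = 0.0327) and su(w[a]) (0.6, adjusted p = 0.0327). 28SrRNA-Psi:CR40741 rose (2.71, adjusted p = 0.0176), which is uncertain because ribosomal copies share reads. mthl8 fell (-1.21, adjusted p = 0.0136) to 25.9 ± 6.89 CPM. stv fell (-0.81, adjusted p = 0.0136), with Act42A (-0.79, adjusted p = 0.00957), Hsp68 (-0.62, adjusted p = 0.0443) and Syngr (-0.59, adjusted p = 0.0333). cry fell from 375 ± 50.9 to 237 ± 12.1 CPM (-0.64, SE 0.13, adjusted p = 0.0327). Ldh was not called (1.32, adjusted p = 0.0558).

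Heat shock genes stood lower in young Marf-mut (median -0.35, adjusted p = 1.82e-08; 0.102 with an estimated correlation), with 2 of 15 fallen and 6 adjusted over the list alone. Proteasome genes stood lower (-0.15, adjusted p = 9.83e-07; 0.46 if estimated), and so did neuropeptide genes (-0.20, adjusted p = 0.0485; 0.331 if estimated). ATF4 targets stood lower (median -0.18, adjusted p = 0.0485; 0.331 if estimated), although the 1 member called when adjusted over the list alone is higher. Ion channel genes stood higher (0.13, adjusted p = 0.00418; 0.517 if estimated), with 5 of 17 adjusted over the list alone. Nuclear genes of the respiratory chain stood higher (0.10, adjusted p = 0.00263; 0.929 if estimated), and cytosolic ribosome genes did too (0.09, adjusted p = 0.039; 0.929 if estimated), which turned lower without replicate 2 of young Marf-mut (adjusted p = 0.854). These medians, with log2 depth as a covariate, turned to -0.05 and -0.09, and 7 of 13 mitochondrial DNA transcripts fell (median -0.376, against -0.069 and none called without it). Innate immune genes stood higher (3 tested, median 0.69, adjusted p = 0.039; 0.331 if estimated), with 2 adjusted over the list alone. The construct markers rose (adjusted p = 5.21e-09; 0.0823 if estimated).

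edgeR called 25 of 7229 genes in young Marf-mut, 15 higher and 10 lower, and DESeq2 called 45. The count was 6 without replicate 1 and 8 without replicate 3 of young Cas9, and 7, 9 and 68 without replicates 1, 2 and 3 of young Marf-mut. Total count scaling gave 36 rising and 15 falling, 70.6% against 60% rising, and log2 depth as a covariate gave 62 calls. Of 14 genes named by rule, y and w kept their calls in every omission and alternative, and cry lost its call in 5 of the omissions.

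Young Opa1-mut against young Cas9 asks the same of the line with guides against Opa1. Ldh rose, with the hexokinase gene Hex-A, and the immediate early genes Arc1 and kay (Fos) rose with them. The cytochrome P450 genes Cyp4p1 and Cyp4p2 rose, as did the small heat shock gene l(2)efl and the replication gene PCNA. The clock gene vri rose, and the core clock list stood higher with a preset correlation but not with an estimated correlation. Of the glial marker genes Gat and alrm fell and the citrate transporter gene Indy rose, and the peptide hormone gene Eh fell.

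In young Opa1-mut y rose (log2 fold change 4.53, adjusted p = 5.21e-06), and Ldh rose (4.19, SE 0.24, adjusted p = 6.27e-06; 309 ± 80.7 against 17.5 ± 4.27 CPM). Arc1 rose (3.14, adjusted p = 0.0148) from 65.6 ± 25.2 to 572 ± 61.6 CPM. Its call ended without replicate 1 of young Cas9 or of young Opa1-mut, with a value of 2.89 to 3.79 over all omissions and alternatives. Cyp4p1 (3.54, adjusted p = 1.82e-05) and Cyp4p2 (3.08, adjusted p = 0.000551) are near-identical copies and are uncertain as separate genes. BomT2 (2.72, adjusted p = 0.000414), PCNA (2.24, adjusted p = 0.00775), l(2)efl (2.05, adjusted p = 2.99e-05) and w (1.57, adjusted p = 1.82e-05) rose. kay (1.14, adjusted p = 0.000574), RpL34b (1.12, adjusted p = 0.00142), kdn (0.99, adjusted p = 0.0366) and Hex-A (0.7, adjusted p = 0.00537) rose, with sgg (0.45, adjusted p = 0.0497), vri (0.45, adjusted p = 0.0248) and Hsp27 (0.42, adjusted p = 0.0417). mthl8 was at least 92.2-fold lower (adjusted p = 1.42e-07). Gat (-0.99, adjusted p = 0.0213), alrm (-0.89, adjusted p = 0.0397), Eh (-0.73, adjusted p = 0.035) and the acetylcholine receptor gene nAChRalpha3 (-0.71, adjusted p = 0.0424) fell. Indy, chosen after its value was seen, rose (1.63, adjusted p = 0.0155). vri lost its call without replicate 3 of young Cas9 or without any single young Opa1-mut library. The clock genes per (0.84, adjusted p = 0.0616) and Clk (0.72, adjusted p = 0.061) were not called.

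Cytosolic ribosome genes stood higher in young Opa1-mut (median 0.23, adjusted p = 5.36e-13; 0.705 with an estimated correlation), with 4 of 84 risen and 10 adjusted over the list alone. This median turned to -0.04 with log2 depth as a covariate. Core clock genes stood higher (0.37, adjusted p = 0.00339; 0.417 if estimated), with 2 of 10 risen and 6 adjusted over the list alone. Glycolysis genes (0.12, adjusted p = 0.0135; 0.639 if estimated) held 2 risen of 12. The Jun kinase genes (0.17, adjusted p = 0.0414; 0.469 if estimated) held 1 of 7, kay. Heat shock genes stood higher (0.21, adjusted p = 0.0135; 0.705 if estimated), with Hsp27 risen. Innate immune genes stood higher (0.59, adjusted p = 0.0414; 0.496 if estimated), with 1 of 3 adjusted over the list alone. Mitochondrial DNA transcripts stood lower (-0.22, adjusted p = 0.0197; 0.817 if estimated), with none of 13 called, and 2 fallen with log2 depth as a covariate (median -0.594). Tricarboxylic acid cycle genes stood lower (-0.15, adjusted p = 0.0135; 0.469 if estimated), while their only called member, kdn, rose. The construct markers rose (adjusted p = 9.3e-06; 0.396 if estimated). The glial list was not called (adjusted p = 0.607), with 1 risen and 2 fallen of 11, and its median (-0.20) and mean (0.03) differ in sign.

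edgeR called 211 of 7166 genes in young Opa1-mut, 163 higher and 48 lower, and DESeq2 called 205. The count was 102, 379 and 71 without replicates 1, 2 and 3 of young Cas9 and 82, 127 and 76 without replicates 1, 2 and 3 of young Opa1-mut. It was 104 with the 12 young libraries in a single fit and 19 with log2 depth as a covariate. Of 31 genes named by rule 13 kept their calls in every omission and 7 under every alternative, and y, Ldh, Cyp4p1, Cyp4p2, w and mthl8 kept their calls throughout.

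Old Drp1-mut against old Cas9 asks what differs at about 35 days in the line with guides against Drp1. Transcripts encoded by mitochondrial DNA, which code for core subunits of the respiratory chain and the ATP synthase, rose. Their calls held after thinning to equal depth, and none held with log2 depth as a covariate or with all 24 libraries in a single fit, although the values of ND4, ND5 and ND1 stayed at 0.56 or above in every alternative. The activity-regulated nuclear receptor gene Hr38 fell, and Drp1 itself fell. The transcriptional regulator gene scribbler (sbb) rose.

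ND4 rose in old Drp1-mut (log2 fold change 0.79, adjusted p = 0.000282) from 1820 ± 89.3 to 3110 ± 543 CPM, and ATP6 rose (0.64, adjusted p = 0.000282) from 9210 ± 108 to 14200 ± 1900 CPM. ND5 (0.7, adjusted p = 8.08e-05), CYTB (0.65, adjusted p = 0.00897) and ATP8 (0.6, adjusted p = 0.0322) rose, and ND1 (0.73), ND4L (0.71) and ND6 (0.67) were called as well. y rose (4.74, adjusted p = 1.45e-11; 171 ± 9.21 against 6.26 ± 2.26 CPM) and sbb rose (0.81, adjusted p = 0.000287). mthl8 was at least 41.8-fold lower (adjusted p = 3.29e-07). The chitin deacetylase gene Cda9 (-3.58, adjusted p = 0.00187), Hr38 (-1.46, adjusted p = 0.00425), Lmpt (-1.14, adjusted p = 0.0428) and jus (-0.75, adjusted p = 0.021) fell. Ldh (0.74, adjusted p = 0.889), vri (0.58, adjusted p = 0.0546) and the stress factor gene Ets21C (-1.8, adjusted p = 0.417) were not called.

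Mitochondrial DNA transcripts stood higher in old Drp1-mut (median 0.64, adjusted p = 1.47e-36; 0.219 with an estimated correlation), with 12 of 13 risen and 13 adjusted over the list alone. The median SE per gene was 0.1. edgeR with log2 depth as a covariate called 0 of the 13 (median 0.42, SE 0.14, 12 at an unadjusted p under 0.05), and with all 24 libraries in a single fit 0 (median 0.64, SE 0.26, 9 at an unadjusted p under 0.05). DESeq2 on the 6 libraries and edgeR after thinning each called 12. Nuclear respiratory chain genes stood lower (-0.10, adjusted p = 3.6e-09; 0.381 if estimated), at -0.19 with log2 depth as a covariate, as did mitochondrial ribosome genes (-0.11, adjusted p = 0.00211; 0.381 if estimated). Tricarboxylic acid cycle genes stood lower (-0.13, adjusted p = 0.0184; 0.381 if estimated). The heat shock list stood lower (-0.08, or -0.197 with log2 depth as a covariate, adjusted p = 0.0188; 0.381 if estimated), with 1 adjusted over the list alone. Mitochondrial dynamics genes stood lower (-0.16, adjusted p = 0.0158; 0.342 if estimated), with Drp1 the 1 fallen member of 12. Core clock genes stood higher (0.27, adjusted p = 0.0127; 0.45 if estimated), with 2 adjusted over the list alone, and this median turned to -0.02 with log2 depth as a covariate. Glial genes stood higher (0.48, adjusted p = 0.0158; 0.439 if estimated), with none of 8 called. The construct markers rose (adjusted p = 2.27e-06; 0.219 if estimated), with 1 of 2 called and 2 adjusted over the list alone.

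edgeR called 27 of 6847 genes in old Drp1-mut, 18 higher and 9 lower, and DESeq2 called 34. The count was 76 without replicate 1 of old Drp1-mut, 12 with all 24 libraries in a single fit, 47 with a replicate block and 5 with log2 depth as a covariate. Leaving out mitochondrial and ribosomal RNA gave 14 calls, 6 rising and 8 falling, 42.9% against 66.7% rising. Of 15 genes named by rule 11 kept their calls in every omission and 2 under every alternative, and y and mthl8 kept their calls throughout.

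Old Marf-mut against old Cas9 asks the same of the line with guides against Marf. The inducible heat shock genes fell together, from the Hsp70 copies to Hsp26, Hsp27 and stv. The clock genes tim and Pdp1 fell, and the peptide gene NPF fell. Mitochondrial DNA transcripts and several nuclear respiratory chain genes fell. Ldh, Arc1 and the tetraspanin gene Tsp42Ed rose. Markers of other cells rose too, Indy and axo of the glial list and the photoreceptor arrestin gene Arr2.

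Hsp70Ab fell in old Marf-mut (log2 fold change -1.3, adjusted p = 8.47e-10) from 1280 ± 117 to 528 ± 36 CPM, and Hsp26 fell (-0.98, adjusted p = 8e-09) from 1440 ± 18.4 to 741 ± 28.2 CPM. Hsp27 (-1.09, adjusted p = 8.15e-09), stv (-1.27), Hsp67Bc (-1.57), Hsp70Aa (-1.55), Hsp70Ba (-1.57), Hsp70Bbb (-1.79) and Hsp70Bc (-1.8) were called too. The copies Hsp70Aa and Hsp70Ab share reads, and so do Hsp70Ba, Hsp70Bbb and Hsp70Bc, so which copy fell is uncertain. tim fell (-0.53, SE 0.09, adjusted p = 0.000299) from 908 ± 78.5 to 639 ± 29.2 CPM, and Pdp1 fell (-0.54, SE 0.08, adjusted p = 6.42e-05) from 1250 ± 39.5 to 870 ± 15.7 CPM. ATP6 fell (-0.68, adjusted p = 4.53e-07) to 5840 ± 584 CPM, with ND5 (-0.5), ND6 (-0.64) and ATP8 (-0.91). The nuclear respiratory chain genes UQCR-6.4 (-0.63, adjusted p = 4e-05), ND-MWFE (-0.55) and ox (-0.66) were called as well. The cuticle-type gene TwdlW (-2.41, adjusted p = 1.38e-08) fell, with mthl8 (-1.77, adjusted p = 0.000159; 15.3 ± 7.81 against 51.3 ± 5.45 CPM). NPF fell (-3.78, SE 0.38, adjusted p = 0.0172) from 2310 ± 349 to 171 ± 73.4 CPM, but young Cas9 libraries alone hold it at 52.9, 1690 and 2530 CPM.

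In old Marf-mut Ldh rose (log2 fold change 2.06, SE 0.24, adjusted p = 0.0109) from 118 ± 27.7 to 504 ± 104 CPM, and Arc1 rose (2.01, adjusted p = 0.0409) from 251 ± 85.3 to 1030 ± 140 CPM. Arc1 is not called without replicate 1 of old Cas9 or without any single old Marf-mut library, at 1.81 to 2.31 over all omissions and alternatives. y (4.18, adjusted p = 2.2e-11), Tsp42Ed (3.28, adjusted p = 8.12e-05), Idgf5 (2.01), dgt2 (1.81), E(spl)m6-BFM (1.8), Indy (1.43, adjusted p = 0.0198) and axo (0.93, adjusted p = 0.0296) rose. Arr2 rose (2.48, adjusted p = 0.00197) from 3.54 ± 1.92 to 21.2 ± 10.8 CPM, which is a marker of another cell type.

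Heat shock genes stood lower in old Marf-mut (median -1.09, adjusted p = 5.15e-31; 0.0929 with an estimated correlation), with 13 of 15 fallen and 14 adjusted over the list alone. Mitochondrial DNA transcripts stood lower (-0.57, adjusted p = 9.14e-22; 0.303 if estimated), with 11 fallen and 13 adjusted over the list alone. The median SE per gene was 0.09. Log2 depth as a covariate left 4 called (median -0.29, SE 0.12), and with all 24 libraries in a single fit edgeR called 0 of the 13 (median -0.56, SE 0.26, 9 at an unadjusted p under 0.05). DESeq2 on the 6 libraries called 13, and edgeR after thinning 10. Nuclear respiratory chain genes stood lower (-0.14, adjusted p = 4.07e-11; 0.385 if estimated), with 12 of 68 fallen and 1 risen, and 18 and 1 adjusted over the list alone. Their median was -0.055 under total count scaling (9 fallen) and -0.074 with log2 depth as a covariate (3 fallen). Core clock genes stood lower (-0.41, adjusted p = 1.15e-05; 0.385 if estimated), with 2 fallen, tim and Pdp1, and 3 adjusted over the list alone. Glial genes stood higher (0.52, adjusted p = 0.000564; 0.385 if estimated), with 2 of 10 risen, Indy and axo, and 3 adjusted over the list alone. Cytosolic ribosome genes stood higher (median 0.09, adjusted p = 0.00658; 0.768 if estimated), while the 3 called members, RpL41 (-0.35), RpL22 (-0.43) and RpL39 (-0.43), fell. Under total count scaling 11 of these ribosome genes rose and 2 fell, and with log2 depth as a covariate their median turned to -0.01. The construct markers rose (adjusted p = 0.00797; 0.385 if estimated), with 1 of 2 called.

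edgeR called 325 of 7090 genes in old Marf-mut, 119 higher and 206 lower, and DESeq2 called 237. The count was 205 without replicate 2 of old Cas9, 201 without replicate 1 of old Marf-mut, 118 with all 24 libraries in a single fit and 138 with log2 depth as a covariate. Total count scaling gave 229 rising and 142 falling, 61.7% against 36.6% rising, so the balance of directions depends on scaling. Of 39 genes named by rule 13 kept their calls under every alternative and 26 in every omission, with tim, Pdp1, Hsp26, Hsp27, stv, Hsp70Ab, Hsp70Aa, Hsp70Bbb, y and dgt2 in both sets.

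Old Opa1-mut against old Cas9 asks the same of the line with guides against Opa1. Most glycolysis genes rose, Hex-A, Pgi and Pfk among them, with Ldh and the trehalose transporter gene Tret1-1, which is also on the glial list. Mitochondrial DNA transcripts fell, with many nuclear respiratory chain genes. Some genes of the ATF4 response (Nmdmc), the unfolded protein response of the endoplasmic reticulum (Xbp1), antioxidant defence (Cat) and Jun kinase signalling (puc) rose, and none of these lists kept its call with an estimated correlation. The synaptic gene Syt1 and the channel gene para fell, and their lists stood lower with a preset correlation but not with an estimated correlation.

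In old Opa1-mut Ldh rose (log2 fold change 3.9, SE 0.14, adjusted p = 5.26e-13) from 118 ± 27.7 to 1790 ± 27.4 CPM, and Tret1-1 rose (3.92, adjusted p = 9.58e-11) from 9.67 ± 4.3 to 150 ± 22.4 CPM. kay rose (2.03, adjusted p = 1.63e-10) from 61 ± 7.84 to 250 ± 19.7 CPM, and Arc1 rose (3.1, SE 0.26, adjusted p = 0.00129) to 2170 ± 171 CPM. y (4.74, adjusted p = 9.15e-13), Vajk3 (4.38, adjusted p = 2.02e-09), Gr58c (3.75), Cyp4p2 (3.92) and Cyp4p1 (3.55) rose, the last pair uncertain as near-identical copies, like snRNA:U6:96Ab (3.23) and snRNA:U6:96Ac (3.02). Nmdmc, a mitochondrial folate enzyme gene of the ATF4 response, rose (1.97, adjusted p = 0.00322), as did Cat (1.37, adjusted p = 2.13e-07), puc (1.12, adjusted p = 1.31e-05), Jafrac1 (1.08, adjusted p = 1.25e-08) and Hex-A (1.06, adjusted p = 2.34e-08). Pfk (0.81), Pgi (0.68), Ire1 (0.78, adjusted p = 0.00235), JhI-21 (0.69), GstD1 (0.61), Xbp1 (0.45), Hsp60A (0.43, adjusted p = 0.00157), Hsc70-3 (0.4), Trxr-1 (0.39), Hsc70-5 (0.37) and crc (0.29, adjusted p = 0.0259) rose. Thor was not called (2, adjusted p = 0.0713).

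ATP6 fell in old Opa1-mut (log2 fold change -1.08, adjusted p = 1.91e-08) to 4400 ± 488 CPM, with CYTB (-1.14), COX3 (-1.22), ATP8 (-1.38) and ND3 (-1.55). The nuclear respiratory chain genes ND-MLRQ (-0.74), ATPsynE (-0.61) and ND-B14.5A (-0.58) and the mitochondrial ribosome genes mRpS21 (-0.89) and mRpS33 (-0.92) were called too. The sodium channel gene para fell (-0.6, adjusted p = 0.000179), with Shab (-0.49), Ih (-0.46), Syt1 (-0.39, adjusted p = 0.00921), VGlut (-0.33) and the active zone gene brp (-0.32, adjusted p = 0.0268). VGlut and brp lost their calls without replicate 3 of old Cas9 or replicate 2 or 3 of old Opa1-mut, brp also without its replicate 1, and both under DESeq2, total count scaling, all 24 libraries or log2 depth as a covariate. Hsp70Ba (-1.45), Hsp70Bbb (-1.01), Hsp70Bc (-0.81) and Hsp70Aa (-0.5, adjusted p = 4e-04) fell, uncertain as near-identical copies. TwdlW (-2.02), Nplp3 (-3.81, adjusted p = 4.74e-05) and mthl8 (at least 82.9-fold lower, adjusted p = 7.89e-10) fell. Capa fell (-8.48, SE 1.55, adjusted p = 0.0402) to 4.63 ± 1.35 from 1640 ± 1340 CPM, and it varies among libraries of a group, with 3140, 278 and 8.48 CPM in old Marf-mut. The clock gene Pdp1 was not called (-0.24, adjusted p = 0.0772).

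Glycolysis genes stood higher in old Opa1-mut (median 0.52, adjusted p = 7.84e-14; 0.115 with an estimated correlation), with 10 of 12 risen and 12 adjusted over the list alone. Log2 depth as a covariate left 4 called at a median of 0.549, where the median SE per gene went from 0.088 to 0.162. ATF4 targets stood higher (0.42, adjusted p = 3.75e-05; 0.115 if estimated), with 6 of 17 risen and 1 fallen, and 9 and 2 adjusted over the list alone. Endoplasmic reticulum stress genes stood higher (0.38, adjusted p = 3.12e-05; 0.115 if estimated), with 6 of 12 risen and 8 adjusted over the list alone. Oxidative stress genes stood higher (0.28, adjusted p = 0.000442; 0.115 if estimated), with 6 of 16 risen and 7 adjusted over the list alone. Jun kinase genes stood higher (0.68, adjusted p = 0.000592; 0.115 if estimated), with 3 of 6 risen, and 4 risen and 1 fallen adjusted over the list alone. One-carbon genes (0.24, adjusted p = 0.00632; 0.118 if estimated) held 2 risen of 10 and 4 adjusted over the list alone. Chaperones of the mitochondrial unfolded protein response (0.25, adjusted p = 0.0348; 0.169 if estimated) held 2 risen of 8, and 2 adjusted over the list alone. Proteasome genes (0.22, adjusted p = 1.56e-05; 0.244 if estimated) held 3 risen of 32, and 3 adjusted over the list alone. Cytosolic ribosome genes (0.10, adjusted p = 0.000592; 0.631 if estimated) held 8 risen of 85 and 6 adjusted over the list alone, 22 risen under total count scaling (median 0.164) and none with log2 depth as a covariate (0.182).

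Mitochondrial DNA transcripts stood lower in old Opa1-mut (median -1.2, adjusted p = 5.27e-25; 0.115 with an estimated correlation), and 13 of 13 fell, also adjusted over the list alone. Nuclear respiratory chain genes stood lower (-0.30, adjusted p = 6.12e-23; 0.143 if estimated), with 38 of 68 fallen and 1 risen, and 50 and 1 adjusted over the list alone. Synaptic genes stood lower (-0.28, adjusted p = 3.12e-05; 0.244 if estimated), with 4 of 16 fallen and 9 adjusted over the list alone, and 3 of the 4 (brp, VGlut and cpx) lost their calls under DESeq2 and total count scaling. Ion channel genes stood lower (-0.33, adjusted p = 0.000116; 0.118 if estimated), with 8 of 17 fallen and 1 risen, and 9 and 1 adjusted over the list alone. The heat shock list stood lower (-0.19, adjusted p = 7e-05; 0.115 if estimated), with 6 of 15 fallen and 7 adjusted over the list alone, and 3 fallen with log2 depth as a covariate (median -0.112). Tricarboxylic acid cycle genes (-0.13, adjusted p = 0.0109; 0.244 if estimated) held 1 risen and 1 fallen of 17. Mitochondrial ribosome genes (-0.10, adjusted p = 0.00622; 0.356 if estimated) held 4 fallen of 72 and 3 adjusted over the list alone. The construct markers rose (adjusted p = 0.00306; 0.118 if estimated), with 1 of 2 called and 2 adjusted over the list alone.

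edgeR called 939 of 7119 genes in old Opa1-mut, 537 higher and 402 lower, and DESeq2 called 625. With log2 depth as a covariate 202 were called, and the fallen nuclear respiratory chain genes went from 38 to 0 (median -0.182, SE 0.162, against -0.303, SE 0.089). Scaling by total count gave 670 rising and 267 falling, 71.5% against 57.2% rising. Of 72 genes named by rule 54 kept their calls in every omission and 24 under every alternative, among the latter Ldh, Tret1-1, kay, puc, Cat, Jafrac1, Hex-A, Pfk, Pgi, ATP6, CYTB, COX3, ATP8 and mthl8.

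**Figure D2:**
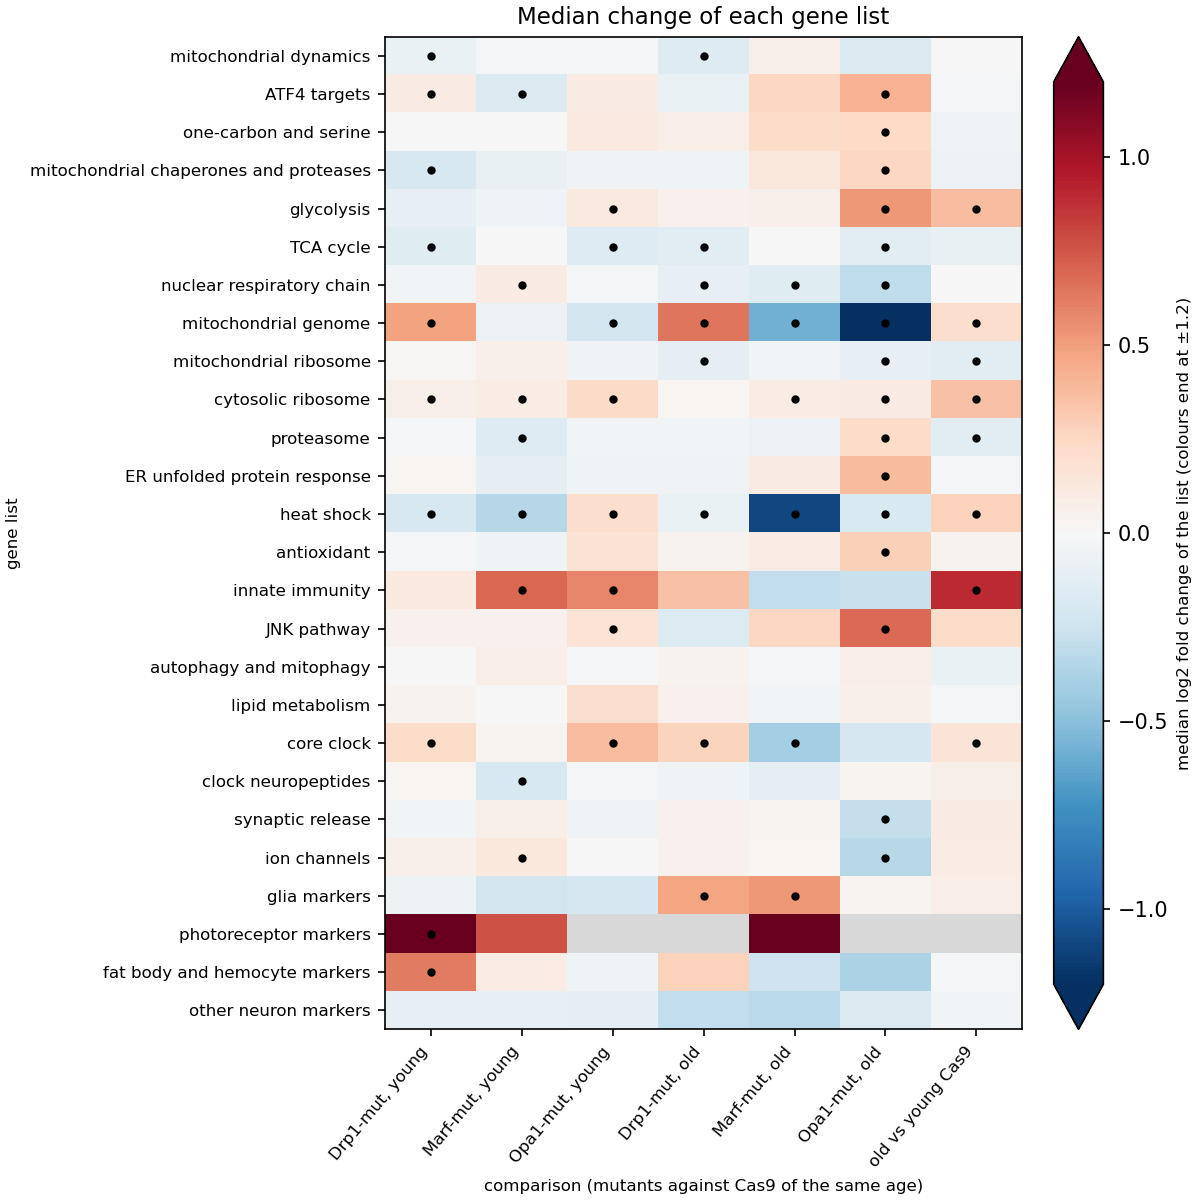
Median log2 fold change of 26 gene lists in the 7 comparisons with Cas9 or between ages. Dots mark camera calls with the preset correlation, and grey cells had fewer than 2 members tested.

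Old Cas9 against young Cas9 asks what changes with age when only Cas9 is expressed. Ldh rose with the glycolysis genes Ald1, Pgi and Tpi. The ribosome genes RpL30 and RpL38 and the antimicrobial peptide genes AttA and AttB rose. The cytosolic ribosome list stood higher with a preset correlation but not with an estimated correlation. The clock gene Clk and the activity-regulated gene Hr38 rose. Tdc2, which encodes the enzyme that makes tyramine in neurons, fell, with the cell surface genes kug and DIP-theta.

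Ldh rose with age in Cas9 (log2 fold change 2.83, SE 0.21, adjusted p = 3.85e-07) from 17.5 ± 4.27 to 118 ± 27.7 CPM, and Clk rose (1.01, adjusted p = 0.0077) from 24.4 ± 0.37 to 47.5 ± 1.16 CPM. dpy (2.64, adjusted p = 1.01e-06), Pka-C3 (1.86, adjusted p = 2.85e-06), lbm (1.94), Tsp42En (1.71), w (1.72, adjusted p = 0.000125), Hr38 (1.66, adjusted p = 0.0178) and AttB (1.15, adjusted p = 0.0256) rose. AttA (0.89), RpL34b (1.06), RpL30 (0.74), RpL38 (0.7), RpL22 (0.61), Ald1 (0.51), Pgi (0.4) and Tpi (0.39) were called, with ATP8 (0.58, adjusted p = 0.0426). snRNA:U6:96Ac (2.62), Hsp70Bb (0.76) and Hsp70Bbb (0.59) rose, uncertain as near-identical copies, and snRNA:7SK rose (1.72). Tdc2 fell (-0.95, adjusted p = 0.000358) from 666 ± 51.3 to 334 ± 58.8 CPM. kug (-0.73), rdo (-0.74), JhI-21 (-0.85), HisRS (-0.69), DIP-theta (-0.62), Act42A (-0.55) and fd59A (-1.43, adjusted p = 0.0407) fell.

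Cytosolic ribosome genes stood higher in old Cas9 (median 0.36, adjusted p = 2.54e-32; 0.59 with an estimated correlation), with 10 of 84 risen and 62 adjusted over the list alone. Glycolysis genes stood higher (0.37, adjusted p = 6.56e-07; 0.532 if estimated), with 4 of 12 risen and 8 adjusted over the list alone. Heat shock genes stood higher (0.28, adjusted p = 1.92e-06; 0.532 if estimated), with 2 risen and 10 adjusted over the list alone. Innate immune genes stood higher (0.89, adjusted p = 0.0178; 0.59 if estimated), with 2 of 3 risen. Mitochondrial DNA transcripts stood higher (0.21, adjusted p = 0.00133; 0.678 if estimated), with 1 risen and 2 adjusted over the list alone, and their median turned to -0.31 with log2 depth as a covariate. Core clock genes stood higher (0.16, adjusted p = 0.0422; 0.641 if estimated), with Clk the 1 called and 3 adjusted over the list alone. None of the ribosome, glycolysis and heat shock genes was called with log2 depth as a covariate, at medians of 0.115, 0.21 and 0.101. Proteasome genes stood lower (-0.13, adjusted p = 0.00417; 0.678 if estimated). Mitochondrial ribosome genes stood lower (median -0.12, adjusted p = 0.0422; 0.713 if estimated), while the 3 called of 72 rose, and 4 rose and 1 fell adjusted over the list alone.

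edgeR called 174 of 7089 genes with age, 151 higher and 23 lower, and DESeq2 called 166. The count was 95, 355 and 68 without replicates 1, 2 and 3 of young Cas9 and 78, 69 and 51 without replicates 1, 2 and 3 of old Cas9, and 364 with a replicate block. Every young Cas9 library is deeper than every old one, and with log2 depth as a covariate no gene was called by edgeR, with 219 at an unadjusted p under 0.05. Scaling by total count gave 125 rising and 90 falling, 58.1% against 86.8% rising, and shifted the median of all genes by -0.117. Of 36 genes named by rule 12 kept their calls in every omission and none under every alternative.

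**Figure D3:**
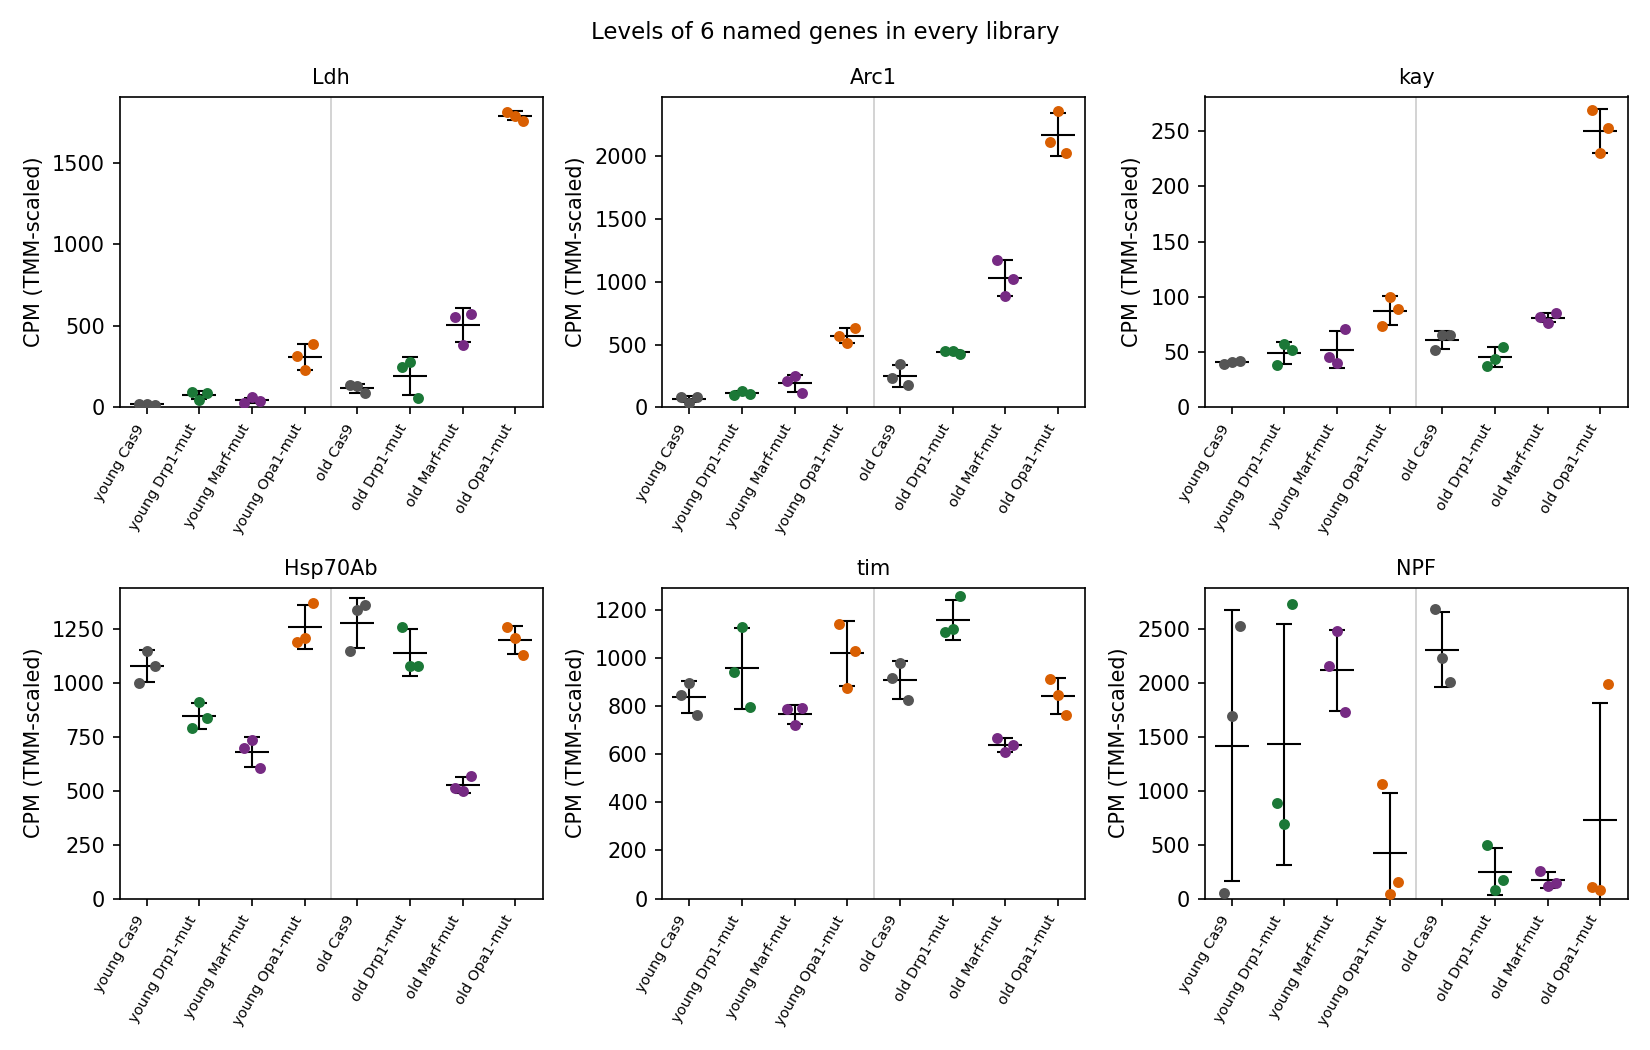
CPM of Ldh, Arc1, kay, Hsp70Ab, tim and NPF in each library of the 8 groups. Bars are means and whiskers are SD (n = 3), and Ldh and Arc1 reach their highest levels in old Opa1-mut.

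An interaction test (old minus young effect) asked whether a mutant effect differs between ages. Such tests share their Cas9 libraries, so a change between Cas9 suspensions enters each with the opposite sign. It cannot be told from a mutant effect that differs between ages. For Opa1-mut the stress and glycolysis genes kay, puc, Pfk and Jafrac1 rose more in old flies. The mitochondrial DNA transcripts ATP6 and COX3 fell more. Opa1-mut is shallower than Cas9 when young and deeper when old, and depth was not tested here. For Marf-mut the heat shock genes Hsp27, Hsp70Ba and Hsp70Bbb had a lower effect in old flies, as did w, and without replicate 3 of young Cas9 edgeR called no gene in this test, with 663 at an unadjusted p under 0.05. In Opa1-mut asrij differs by 1.31 (adjusted p = 3.98e-05), TrpRS by 1.41 (adjusted p = 0.000976), ND4L by -1.19 (adjusted p = 0.000976), ATPsynE by -1.32 (adjusted p = 1.38e-05) and snRNA:7SK by -2.69 (adjusted p = 0.000689). In Marf-mut Cirl differs by -0.78 (adjusted p = 0.0134), Ythdc1 by -1.23 (adjusted p = 0.0082), su(w[a]) by -0.81 (adjusted p = 0.019), snRNA:7SK by -2.23 (adjusted p = 0.0145) and 28SrRNA-Psi:CR40741 by -3.86 (adjusted p = 0.0082). Only Aldh (1.81) and eIF3f1 (0.67) have a higher Marf-mut effect in old flies (adjusted p = 0.0222 each), chosen after their values were seen.

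For Opa1-mut edgeR called 417 of 7411 genes in the interaction, 175 higher and 242 lower, and DESeq2 called 358. Total count scaling gave 289 higher and 193 lower, 60% against 42% higher, and shifted the median of all genes by 0.121. The count was 277 without replicate 1 and 270 without replicate 3 of young Cas9, 277 without replicate 2 of young Opa1-mut, 259 without replicate 3 of old Cas9, and 255, 275 and 232 without replicates 1, 2 and 3 of old Opa1-mut. For Marf-mut edgeR called 21 of 7385, 2 higher and 19 lower, and DESeq2 called 51. Omitting young Cas9 replicates 2 and 3 in turn gave 40 and 0, young Marf-mut replicates 1, 2 and 3 gave 13, 9 and 140, old Cas9 replicates gave 12, 10 and 5, and old Marf-mut replicates gave 4, 3 and 10. For Drp1-mut edgeR called 0 of 7256, with 260 at an unadjusted p under 0.05 where 363 are expected, and DESeq2 called 3. Without replicate 1 or 2 of young Cas9 or replicate 3 of young Drp1-mut 1 gene was called, and total count scaling gave 1 higher and 2 lower.

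Marf-mut and Opa1-mut were compared directly to ask whether the lines with guides against fusion genes differ. In young flies the heat shock genes stood lower in Marf-mut, 14 of 15 with a median of -0.56 and 5 called, and Ldh stood lower (log2 fold change -2.87, adjusted p = 0.0115). Cyp4p2 (-4.41, adjusted p = 0.000172), Cyp4p1 (-3.8), the stress gene TotA (-2.49), PCNA (-2.04), cv-2 (-1.8), Gart (-1.78) and sick (-1) were lower in Marf-mut. mthl8 was at least 37.9-fold higher in Marf-mut (adjusted p = 0.000172), and Dhc98D (4.2), DIP-zeta (1.1), Eip78C (0.91) and jus (0.9) were higher. In old flies 15 of 15 heat shock genes stood lower in Marf-mut, with a median of -0.78 and 11 called, among them Hsp26 (-1.1, adjusted p = 9.86e-10) and Hsp70Ab (-1.19). kay (-1.63, adjusted p = 7.73e-11), Thor (-2.18, adjusted p = 0.00758), dl (-2.46), Tret1-1 (-2.79) and TotA (-3.15) were lower in Marf-mut, and Vajk3 was at least 104-fold lower (adjusted p = 1.08e-10). The insulin-like gene Ilp5 (7.19, adjusted p = 0.0161), Akh (2.43), acj6 (3.35), the opsin gene Rh2 (3.2) and Arr2 (2.17) were higher in Marf-mut. Ilp5, Akh and Rh2 are known from insulin-producing cells, the corpora cardiaca and the ocelli. mthl8 was at least 24.7-fold higher in old Marf-mut (adjusted p = 1.72e-05).

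edgeR called 99 of 7148 genes between young Marf-mut and Opa1-mut, 37 higher and 62 lower in Marf-mut, and DESeq2 called 94. The count was 38, 59 and 182 without replicates 1, 2 and 3 of young Marf-mut, and 32 and 30 without replicates 1 and 3 of young Opa1-mut. Of 22 genes named by rule 7 kept their calls in every omission. In old flies edgeR called 1154 of 7244, 492 higher and 662 lower in Marf-mut, and DESeq2 called 620, and 20 of 24 named genes kept their calls in every omission.

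Fission was set against fusion by comparing Drp1-mut with the mean of Marf-mut and Opa1-mut. In old flies the mitochondrial DNA transcript ND1 stood higher in Drp1-mut (log2 fold change 1.4, adjusted p = 5.69e-09). Arc1 (-1.72, adjusted p = 1.74e-11), kay (-1.65, adjusted p = 8.09e-08), path (-1.35) and asrij (-1.22) stood lower. edgeR called 650 of 7352 genes, 357 higher and 293 lower, and DESeq2 called 552. Without replicate 2 of old Drp1-mut 399 were called. Total count scaling gave 161 higher and 668 lower, 19.4% against 54.9% higher, and shifted the median of all genes by -0.145. In young flies edgeR called 1 of 7293, CG15784 (-1.74, adjusted p = 0.0126), chosen after its value was seen, with 547 at an unadjusted p under 0.05 and 14 called by DESeq2. That count was 0 without Drp1-mut replicate 1 or 2, Marf-mut replicate 2, or Opa1-mut replicate 1 or 3. It was 3 and 8 without replicate 3 of Drp1-mut and of Marf-mut. Total count scaling gave 1 higher and 5 lower, 16.7% against 0% higher.

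Genes called at both ages in the same mutant were counted next. y and mthl8 are called in all 6 comparisons with Cas9, out of 1244 genes called at least once. For Drp1-mut 4 genes changed in the same direction at both ages against 0.01 expected, mthl8, CG34423, y and lncRNA:CR46393. For Marf-mut 12 did against 0.51 expected, among them y, mthl8, stv, Hsp68, Nhe3 and Syngr. For Opa1-mut 67 did against 14.3 expected, with 14 in opposite directions, and Ldh, Arc1, kay and Hex-A are among the 67. Across genes, the fold changes of young and old correlate at 0.387 for Drp1-mut, 0.19 for Marf-mut and 0.315 for Opa1-mut, and genes are not independent replicates.

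Mutants of an age share Cas9 libraries, which may cause part of an excess of shared calls. In 20 simulations of young flies with only the controls shared, Drp1-mut and Marf-mut shared 0 calls on average and 0 at most, against 3 observed (y, w and mthl8) and 0.01 expected, with a covariance of 0.0464 observed and 0.0401 simulated (0.0471 at most), so this covariance does not exceed the simulated ones. Drp1-mut and Opa1-mut shared 6 against 0.1 expected, 0.1 on average and 2 at most simulated, with a covariance of 0.098 against 0.0389 (0.0438 at most). Marf-mut and Opa1-mut shared 5 (y, w, mthl8, BomT2 and kdn) against 0.3 expected, 0.05 on average and 1 at most simulated, with a covariance of 0.0791 against 0.0391 (0.0444 at most). In old flies Drp1-mut and Marf-mut shared 6 against 0.51 expected, 0.15 on average and 2 at most simulated, with a covariance of 0.0436 against 0.0333 (0.04 at most). A further 11 genes went in opposite directions, 10 of them mitochondrial DNA genes. Drp1-mut and Opa1-mut shared 7 against 1.74 expected, 0 on average and 0 at most simulated, with a covariance of 0.0613 against 0.033 (0.0439 at most), and 12 mitochondrial DNA genes went in opposite directions. Marf-mut and Opa1-mut shared 144 against 19.4 expected, 0.05 on average and 1 at most simulated, with a covariance of 0.0995 against 0.0351 (0.0412 at most), and 4 went in opposite directions. The correlation across genes was below the simulated mean for Drp1-mut with Marf-mut in young (0.426 against 0.502) and old flies (0.354 against 0.49) and for old Drp1-mut with Opa1-mut (0.366 against 0.49). A shift of the Cas9 suspension was not simulated and stays open. The 3 controls of an age cannot form separate sets of 2 or more, so their share was not removed.

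With 1 value per suspension, 8 suspensions and 3 residual degrees of freedom, each mutant was tested over both ages. Arc1 rose in Marf-mut (log2 fold change 1.71, adjusted p = 0.00415) and Opa1-mut (3.08, adjusted p = 5.87e-05), and y rose in Drp1-mut (4.73, adjusted p = 1.25e-06), Marf-mut (4.19, adjusted p = 3.52e-06) and Opa1-mut (4.61, adjusted p = 1.5e-06). Nplp1 (1.37) and Ilp5 (4.07) rose in Marf-mut, snRNA:U6:96Ac (2.94) rose in Opa1-mut, and mthl8 fell in Opa1-mut (adjusted p = 0.000496). Digestive enzyme genes such as Jon99Cii (5.45, adjusted p = 0.000633) and Jon99Ci (5.88) rose in Drp1-mut, and Cyp4g1, known from oenocytes, fell (-4.28). They rest on single libraries, with Jon99Cii at 651 CPM in replicate 1 of young Drp1-mut and Cyp4g1 at 512 CPM in replicate 3 of young Cas9. The odorant binding protein gene Obp19d rose in Marf-mut (6.02) and Opa1-mut (9.91), with 1120 CPM in replicate 2 of young Opa1-mut. Ilp5 stands at 23.1, 0 and 0 CPM in young Marf-mut, Nplp1 is high in replicate 3 of each Marf-mut group alone (2540 and 4590 CPM), and of the 5 named Marf-mut calls only y held in every omission. Heat shock genes stood lower in Marf-mut, 15 of 15 with a median of -0.74 and 1 called, stv (-1.01, adjusted p = 0.0355).

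Of 8707 genes edgeR called 12 in Drp1-mut, 9 higher and 3 lower, 9 in Marf-mut, 6 higher and 3 lower, and 53 in Opa1-mut, 46 higher and 7 lower. DESeq2 called 28, 47 and 114. For Drp1-mut the count was 2 without the young Cas9 suspension, 6 without young Drp1-mut, 34 without young Opa1-mut, 19 without old Drp1-mut and 35 without old Opa1-mut. For Marf-mut it was 14 without young Drp1-mut, 48 without young Opa1-mut, 48 without old Opa1-mut and 5 without old Marf-mut. For Opa1-mut it was 13 without young Cas9, 84 without young Drp1-mut, 209 without young Opa1-mut, 83 without old Drp1-mut, 131 without old Opa1-mut and 26 without old Cas9.

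The authors' deposited comparison tables call 18, 76 and 219 genes in young Drp1-mut, Marf-mut and Opa1-mut and 43, 199 and 637 in the old ones. Of the calls made here 6, 19 and 151 in young and 26, 180 and 587 in old flies are among them with the same direction. Their target values are -0.54 (padj 0.162) for Drp1, -0.25 (padj 0.745) for Marf and -0.46 (padj 0.0546) for Opa1 in young flies. In old flies they are -0.89 (padj 3.46e-05), -0.28 (padj 0.608) and -0.69 (padj 7.92e-05).

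Autophagy and mitophagy genes were not called as a list in any comparison, with a lowest adjusted p of 0.516 (with age). Lipid metabolism genes were not called either (lowest adjusted p 0.529, young Opa1-mut), nor were markers of other neurons (lowest adjusted p 0.0623, old Drp1-mut). Photoreceptor genes could be tested as a list in 3 comparisons only. The 70 list calls all rest on the preset correlation between genes, and with an estimated correlation 0 remain.

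**Figure D4:**
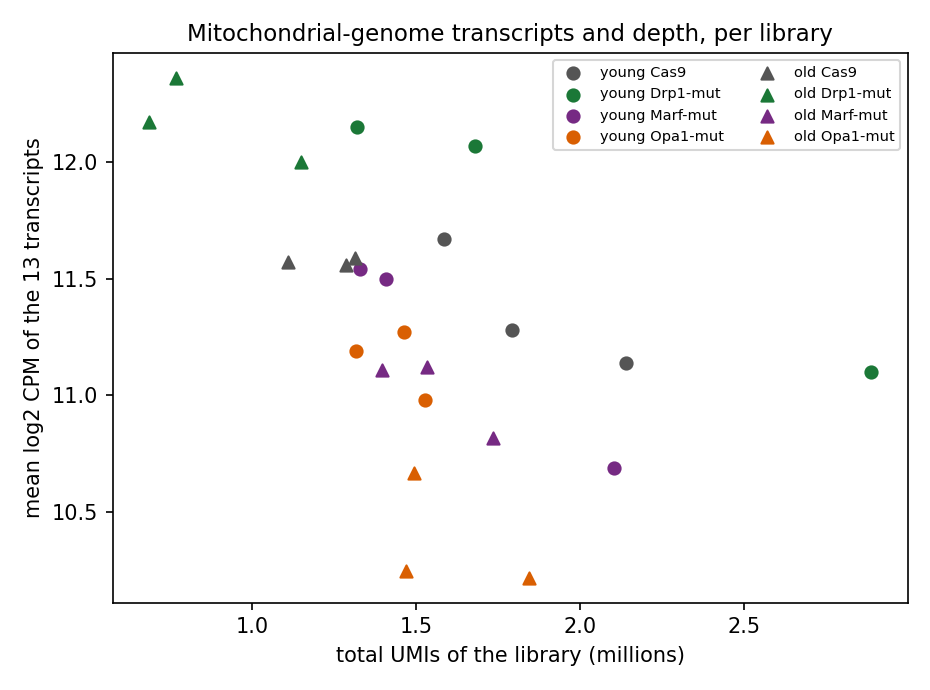
Mean log2 CPM of the 13 mitochondrial DNA transcripts against total UMIs of each library. Circles are young and triangles old, and colours give the genotype.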

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

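These results come from the interaction test (old minus young log2 fold change). Of the tests of explanations, the one of neighbouring genes and the splits of the Opa1-mut interaction and of the comparisons between mutants were set before the results were seen, and all others were chosen after.

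Of the 417 genes in Opa1-mut, the named ones with a higher effect in old flies are TrpRS (1.41), asrij (1.31), puc (0.97), kay (0.88), Pfk (0.8), JhI-21 (0.72), Jafrac1 (0.7), Pdi (0.53), Xbp1 (0.53), Pgi (0.5) and Hsp60A (0.45). Those with a lower effect among mitochondrial DNA transcripts are CYTB (-0.84), ATP6 (-0.86), COX3 (-0.93), ND4L (-1.19), ND3 (-1.44), ATP8 (-1.45) and trnC (-4.24). Among nuclear respiratory chain and mitochondrial ribosome genes they are ND-B14.5A (-0.75), ND-MLRQ (-1.19), ATPsynE (-1.32), mRpL36 (-0.81), mRpS33 (-1.23) and mRpS21 (-1.51). Among heat shock and ribosomal genes they are Hsp27 (-0.49), Hsp70Bc (-1.01), Hsp70Ba (-1.83), RpL38 (-0.77), RpL34b (-1.15), pre-rRNA:CR45847 (-2.66) and 5.8SrRNA-Psi:CR45863 (-5.17). The clock genes Pdp1 (-0.48), sgg (-0.71) and Clk (-1.2) have lower effects too. So do Shab (-0.66), REPTOR-BP (-0.73), w (-1.12), kdn (-1.65) and snRNA:7SK (-2.69). With log2 depth as a covariate nuclear respiratory chain medians were -0.218 young and -0.182 old, against -0.026 and -0.303. Mitochondrial DNA medians were -0.59 and -0.97, against -0.22 and -1.2. Of the 21 genes in Marf-mut, the named ones are Hsp27 (-0.74), Cirl (-0.78), su(w[a]) (-0.81), ND-MWFE (-1.21), Ythdc1 (-1.23), Hsp70Ba (-1.43), w (-1.49), Hsp70Bbb (-1.58), snRNA:7SK (-2.23) and 28SrRNA-Psi:CR40741 (-3.86).

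Of 100 splits of the 12 libraries, 2 called as many genes as the Opa1-mut interaction (real 417, highest other 757) and 6 as many as the Marf-mut interaction (real 21, highest other 287). Only the first share is under 0.05, and splits of pools cannot exclude chance differences between suspensions. For Drp1-mut (real 0, highest other 130) all 100 call as many by definition and decide nothing. The top splits set apart old Cas9 (757) and old Marf-mut libraries (287), so they follow groups. Of 84 splits, 2 called as many genes as Drp1-mut against the fusion mutants in old flies (real 650, highest other 1041, Opa1-mut libraries against the rest). This share is under 0.05, with the same limit. In young flies 14 did (real 1, highest other 89, Marf-mut libraries against the rest), a share above 0.05.

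With 10 splits the other comparisons have too few for a share under 0.05. The real count and the highest other are 6 and 207 in young Drp1-mut, 25 and 123 in young Marf-mut, 211 and 4 in young Opa1-mut, 27 and 2 in old Drp1-mut, 325 and 3 in old Marf-mut and 939 and 3 in old Opa1-mut. They are 174 and 2 for age in Cas9, and 99 and 2 in young and 1154 and 1 in old flies between Marf-mut and Opa1-mut. In young Drp1-mut and young Marf-mut 2 splits called as many genes as the real one, and in the rest 1, the real one itself. The splits with 207 and 123 set the 3 deepest libraries (young Cas9 replicates 1 and 3 with replicate 3 of the mutant) against the 3 shallowest, which points to a structure by depth in these young libraries. The highest other split of old Drp1-mut is by depth too and called 2 genes. Its sides mix genotypes, so it decides nothing on depth.

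The first pattern is the genes changed at both ages in a mutant, y and mthl8 among them. A candidate explanation for y is that the guide constructs carry it, since its log2 fold changes in the 3 mutants differ by at most 0.56 at an age. Line background linked to the inserts was tested on the 67 genes of Opa1-mut alone and stays open, as 22 of the 66 with a position have another within 250 kb, against a median of 18 and a 95th percentile of 25 in random sets. For mthl8, without UMIs in Drp1-mut and Opa1-mut, a deletion of both copies reaching lncRNA:CR45402, 99.1 kb away, is excluded, because this gene stays present (lowest log2 fold change 1.8, SE 0.26, in Opa1-mut, higher at both ages, and -0.47, SE 0.43, in Drp1-mut). A shorter deletion stays open, because 0 of the 8 genes nearer to mthl8 were tested, in a window widened from 25 to 100 kb after the narrower one was seen. An effect of mitochondrial form on these genes was not tested apart from the line that carries it.

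The second pattern is the mitochondrial DNA transcripts in old mutants, higher in Drp1-mut and lower in Marf-mut and Opa1-mut. The slope on depth within groups (-0.878 per log2 unit) predicts 79.4% of the difference from old Cas9 in Drp1-mut (95% interval 53 to 105.8), 51.6% in Marf-mut (34.5 to 68.8) and 27.1% in Opa1-mut (18.1 to 36.2), and the criterion on these intervals was given after the values were seen. Depth may account for a part or all of the change in Drp1-mut, stays open as a part in Marf-mut, and is excluded as the whole cause in Opa1-mut, where 11 of 13 stay called with depth as a covariate (median -0.97 against -1.2). With this covariate 4 of 11 calls remain in Marf-mut (median -0.29, SE 0.12, against -0.57, SE 0.09) and 0 of 12 in Drp1-mut by edgeR (0.42, SE 0.14, against 0.64, SE 0.1, with 12 at an unadjusted p under 0.05), so the calls ended with a smaller fold and a larger SE. After thinning to equal depth 12, 10 and 13 are called in Drp1-mut, Marf-mut and Opa1-mut (medians 0.63, -0.57 and -1.2). The slope stays at -0.901, so thinning decides nothing on depth. Suspension and genotype cannot be told apart by design, the tests by suspension decide nothing here (0 of 13 called by edgeR and by DESeq2 in each mutant, 2 at an unadjusted p under 0.05 in Opa1-mut), and an effect of the mutants on mitochondrial DNA or its transcription stays open, untested.

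The third pattern is the lower heat shock genes in Marf-mut. An unusual old Cas9 suspension is excluded as the whole cause, because against old Opa1-mut their median is -0.78 too. A single unusual Marf-mut suspension stays open, although the other one is lower too, with 15 of 15 against young Cas9 (median -0.35, 2 called) and 14 of 15 against young Opa1-mut, which shares no library with Cas9 (median -0.56, 5 called). The young suspensions without Marf guides also differ, with 13 of 15 lower in Drp1-mut (median -0.19, 0 called) and 4 in Opa1-mut (median 0.21), so a part of the -0.56 comes from Opa1-mut. The median is -1.09 in old flies (13 called) and -0.35 in young ones (2 called), and this difference was not tested for the list. A difference of line background or of handling that both Marf-mut suspensions share was not tested, and an effect of Marf loss stays open beside it.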

How the results depend on the processing

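The 12-library fit, leaving out mitochondrial and ribosomal RNA, and the depth covariate were chosen after seeing the data, the other alternatives before. Leaving out a library at a time moved the counts of called genes to 2–43 in young Drp1-mut, 6–68 in young Marf-mut, 71–379 in young Opa1-mut, 24–76 in old Drp1-mut, 201–468 in old Marf-mut, 647–858 in old Opa1-mut and 51–355 with age. It moved the interactions to 0–1 for Drp1-mut, 0–140 for Marf-mut and 232–536 for Opa1-mut, Marf-mut against Opa1-mut to 30–182 in young and 794–1158 in old flies, and Drp1-mut against the fusion mutants to 0–8 and 399–738. Leaving out a suspension moved the suspension tests to 2–35, 5–48 and 13–209. The targets moved to -0.68 to -0.36 (Drp1), -0.42 to -0.15 (Marf) and -0.65 to -0.36 (Opa1) in young flies, and to -1 to -0.76, -0.32 to -0.22 and -0.7 to -0.66 in old ones. The number of called lists moved to 56–72. Without a filter on low counts the calls are 82, 141 and 594 in young Drp1-mut, Marf-mut and Opa1-mut, 93 in old Drp1-mut, 343 with age, 10 and 127 in the Drp1-mut and Marf-mut interactions, 327 between young Marf-mut and Opa1-mut, and 12 in young Drp1-mut against the fusion mutants. In the suspension tests they are 48, 65 and 184. Young Opa1 is then called (-0.48), and shared calls are 14, 41 and 139 across ages, 28, 45 and 56 between young mutants, and 22 and 31 between old Drp1-mut and the old fusion mutants. With DESeq2 the calls are 12 in young Drp1-mut, 45 in young Marf-mut, 625 in old Opa1-mut, 3 and 51 in the Drp1-mut and Marf-mut interactions, 14 in young Drp1-mut against the fusion mutants, and 620 between old Marf-mut and Opa1-mut. DESeq2 also gives 28, 47 and 114 by suspension, and shared calls of 23 across ages in Marf-mut and 5, 10 and 16 between young mutants. With all 24 libraries in a single fit the calls are 14 and 55 in young Drp1-mut and Marf-mut and 12 and 118 in the old ones, and young Opa1 is called (-0.46). With log2 depth as a covariate they are 20, 62 and 19 in young and 5, 138 and 202 in old flies. With age they are 0 (edgeR, with 219 at an unadjusted p under 0.05), with Ldh at 2.62 or above. The calls of old Drp1 (-0.78) and old Opa1 (-0.58) end. Total count scaling gives 51 in young Marf-mut, 3 in the Drp1-mut interaction, 6 in young Drp1-mut against the fusion mutants, 14 in Marf-mut by suspension, and shared calls of 21 across ages in Marf-mut and 18 between young Marf-mut and Opa1-mut. Thinning to equal depth gives 15 in young Marf-mut, 3 and 341 in Drp1-mut against the fusion mutants, young and old, and 19 in Marf-mut by suspension. The replicate block gives 82 in young Marf-mut, 47 in old Drp1-mut, 364 with age and 11 in young Drp1-mut against the fusion mutants, although same-number libraries do not pair (correlation across genes -0.141 to 0.116). The 12 libraries of an age in a single fit give 104 in young Opa1-mut, and leaving out mitochondrial and ribosomal RNA gives 14 in old Drp1-mut. With an estimated correlation 0 of 70 list calls by camera remain. The cytosolic ribosome list turned direction in young Drp1-mut without its replicate 1 and in young Marf-mut without its replicate 2. The adjusted p of this list moved to 1.02e-14–0.948 and 1.74e-15–0.901 when a library was left out. Except where fewer libraries or fewer genes enter a fit, the cause was not tested. Among calls of named genes, total count scaling kept 271 and ended 16, DESeq2 size factors kept 286 and ended 1, DESeq2 kept 256 and ended 31, no filter kept 284 and ended 3, and thinning kept 248 and ended 36. The replicate block kept 255 and ended 17, all 24 libraries kept 121 and ended 90, 12 libraries kept 125 and ended 50, leaving out mitochondrial and ribosomal RNA kept 184 and ended 2, and the depth covariate kept 82 and ended 129. Omitting single libraries or suspensions kept 1387 and ended 438, and none of these called genes turned direction under any alternative run.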

Other observations

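Peptide genes vary among libraries sorted from a single suspension. NPF stands at 52.9, 1690 and 2530 CPM in young Cas9, and at 251 ± 221 in old Drp1-mut and 726 ± 1090 in old Opa1-mut (SD, n = 3). Capa stands at 12.3, 743 and 4.05 CPM in young Cas9 and 210, 2870 and 1830 in old Cas9. Dsk stands at 188, 4170 and 4050 CPM in old Cas9 and at 20.1 ± 8.78 in young Marf-mut. Nplp1 stands at 2540 CPM in replicate 3 of young Marf-mut and 4590 in replicate 3 of old Marf-mut. The insulin-like genes stand at 230 ± 134 (Ilp2), 128 ± 11.9 (Ilp3) and 42.5 ± 26.9 CPM (Ilp5) in old Marf-mut, and Ilp3 at 28.9 ± 21.9 in old Cas9.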
